A study of Mus musculus with 6 samples.

How the data were processed

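Total RNA was extracted from synovial tissue around the ankle joints of male DBA/1 mice, an inbred strain prone to arthritis after immunization with type II collagen. Per the labels' protocols, mice aged 6 to 8 weeks received 100 µg of bovine type II collagen in complete Freund's adjuvant, with a boost 2 weeks later in a hind footpad. The boosted foot was left out, the skin was removed, and RNA was taken from pooled tissues with a mean RNA integrity number of 9.5 over all samples. Samples were taken at week 6, 9 and 15 after immunization, which the series names as induction, peak and resolution. Each week had 2 arrays, 6 in all, labelled with Cy3-streptavidin. The labels do not say whether both arrays of a week hold RNA of different pools of animals, so p-values measure only the spread between these arrays, which may be technical.

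The deposited signal table holds 1 intensity per probe and array on a linear scale with no detection p-value, per the file headers. Its normalization is not given in the sources used here, and its values show no background subtraction and a different distribution on each array. The authors' processed values of the same arrays are log2 values with a median between 6.732 and 6.734 on every array. Their scaling method is not given in the sources used here. Each column of them correlated best with the log2 intensities of its own array, with Pearson's r across probes from 0.9958 to 0.9992, against at most 0.9922 for any other array. These values served as an alternative. The signal table also has 2 columns of per-sample values that match no sample here, and they were not used here. No untreated mice were analysed here, and no slide or scan date was given for any array.

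The signal table has 26821 rows, of which 25697 carry a probe ID. The other 1124 rows have none and were taken as control rows. Those brighter than the median by over 5 median absolute deviations on any array, 13 rows, were left out, and the other 1111 served as the background set. A probe's detection p on an array was the share of background rows at or above its signal. Intensities were background-corrected with the normal-exponential model from the background set, with an offset of 16, quantile-normalized and log2-transformed (neqc of limma 3.58.1 in R 4.3.3). A probe was tested when its detection p was under 0.05 on at least 2 of the 6 arrays, which left 13633 probes. The probe with the highest mean over all arrays stood for its gene, and probes without a symbol stayed in as features of their own. This gave 10167 features, 9360 with a symbol and 807 without. The probe table named 1 gene for 23978 probes, several for none and no gene for 1719. Of the named probes, 23962 matched a gene ID of the RefSeq table of the mouse assembly GRCm38.p6, used for names only, and no symbol had to be updated. No genome build is named for the probes, so no coordinates are given.

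The median intensity ranged from 99.07 on the second week 15 array to 129.5 on the first week 6 array, against a mean of the background rows from 86.88 to 111.2. Between 47.88% and 50.73% of probes were detected per array. With 2 arrays per group, the number of arrays limits the precision.

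All 6 arrays were fitted in 1 linear model with group means (limma lmFit and eBayes), which left 3 residual degrees of freedom and 4.04 prior degrees of freedom. Every p-value is two-sided, and every adjusted p of a gene comes from limma with Benjamini-Hochberg adjustment over the 10167 features, with a threshold of 0.05. A moderated F test covered any change over the 3 weeks. Lists of genes, 34 in all, for cell types, tissues and pathways were fixed before the data were examined and tested with limma's camera, a competitive test of a list against all other genes, with a preset inter-gene correlation of 0.01. Adjustment was over the 34 lists of a comparison. Camera with an estimated correlation and fry, a test of whether the genes of a list move on balance one way, were alternatives. Fold changes are on the scale after background correction and an added offset, and most are smaller with other background corrections, so a lower bound holds on this scale only. Where a gene was not above background on either array of a group, its fold is a lower bound, written as at least. The bound compares the bright group's mean with the dim group's mean of, per array, the higher of the lowest signal among detected probes and the gene's own signal.

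Genes were named by a rule fixed together with the lists: per comparison the 12 largest positive and the 12 largest negative changes past the threshold, leaving out predicted and clone-only symbols, the 4 members with the smallest p of each list called, and a set of arthritis and reference genes chosen by name. Of that set, Il6, Cxcl5, Ccl2, Acan and Alox15 did not pass the detection filter and were not tested, and Prg4 and Spp1 have no probe named here. Genes named outside this rule are said to be so.

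The fit was tested on 20 simulated data sets of 10167 features for the comparison of week 9 with week 6, each with 200 changed genes. It recovered 65.3% of genes changed by 1 on the log2 scale and 99.7% of those changed by 2, and 5.86% of its calls were false. The cell cycle list was also shifted by 0.5 in each set, and its calls were not counted as false. Simulated genes varied independently and with the same spread in every week. The week 15 arrays differed more than the other pairs, so these rates may not hold for the real arrays. Alternatives were no background correction, a normal-exponential correction fitted on the probes with an offset of 50, scaling to the 75th percentile, cyclic loess, the authors' values, no filter and a stricter filter on dim probes, every probe on its own, a variance trend with robust estimation, a fit of only the 4 arrays compared, the replicate number as a block, each array left out in turn, and other thresholds. Bootstrap intervals in the closing section used 10000 draws of genes.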

Results

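Gene expression in synovial tissue was measured on Illumina bead arrays at 3 times in collagen-induced arthritis, a mouse model of rheumatoid arthritis in which immunization with type II collagen leads to joint inflammation. Week 6 stands for induction, week 9 for the peak and week 15 for resolution, with 2 arrays of pooled tissue each. Arrays of 1 week agreed closely at week 6 and week 9, with Pearson's r across genes of 0.991 for both pairs. The pair at week 15 agreed less, with r of 0.975 across genes, and its log2 differences had an SD of 0.510 against 0.299 at week 6. The first week 15 array correlated better with both week 6 arrays, at 0.9825 and 0.9844, than with the second week 15 array. The second week 15 array was also dimmer, with a median intensity of 99.07 against 123.9 on the first. Genes are not independent replicates, so these correlations describe the arrays only.

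Lymphocyte genes had bright signals on every array. The signals of different probes also depend on how well each probe binds, so a percentile ranks signals and not amounts of RNA. Percentiles were taken among all genes, each by its brightest probe, together with the probes without a symbol. The median percentile of the level was 88.6 for the list of B cell and plasma cell genes, 84.1 for T and NK cell genes and 82.8 for dendritic cell and MHC class II genes. General lists lay higher, with 99.7 for ribosomal protein genes and 95.4 for oxidative phosphorylation genes. Of the 21 B cell and plasma cell genes on the array, 17 were detected on all 6 arrays, and so were 21 of 26 T and NK cell genes. Cartilage genes lay at a median percentile of 28.7, with 2 of 28 detected on all 6 arrays. Osteoblast and osteocyte genes lay at 29.9, with 3 of 25 detected. The collagens and matrix genes were between these, with 20 of 37 detected. Skeletal muscle genes had a median log2 signal of 8.47 on the first week 15 array and between 4.74 and 4.92 on the other 5. Acta1, the skeletal muscle actin, was chosen after its values were seen and had a log2 signal of 11.46 on that array and 4.37 on the second week 15 array.

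**Figure D1:**
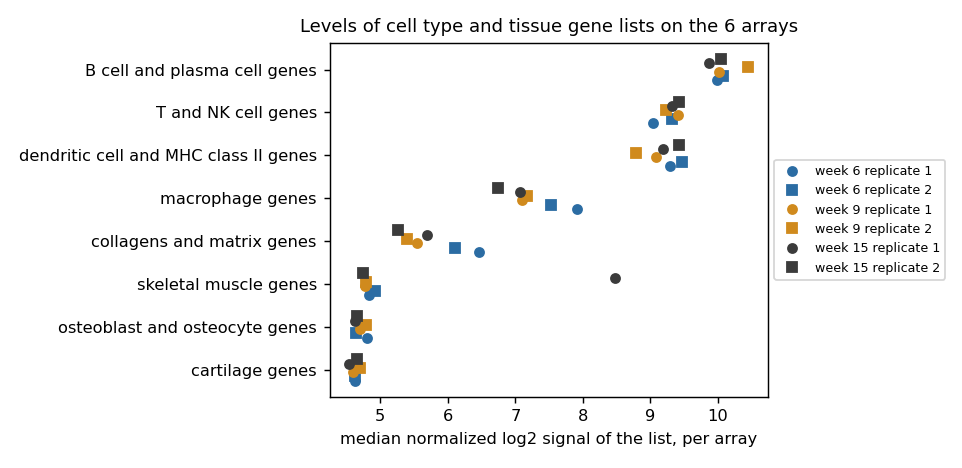
Median normalized log2 signal (horizontal axis) of the genes of 8 lists (vertical axis), with 1 point per array, coloured by week and shaped by replicate. The B cell list lies between 9.87 and 10.45 and the cartilage list between 4.54 and 4.70 on the 6 arrays, and the skeletal muscle list stands apart on the first week 15 array at 8.47.

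The comparison of week 9 with week 6 asked how the tissue at the peak differed from that at induction. The fat cell genes Adipoq and Cidea, the adhesion gene Vcam1 and the protease gene Plau were lower at week 9, while the heat shock gene Hspa1a and the immediate early gene Fos were higher. Adipoq, which encodes the fat cell hormone adiponectin, fell from a log2 signal of 8.11 ± 0.19 to 5.38 ± 0.30 (SD, n = 2), a change of -2.72 with a standard error of 0.27 (limma adjusted p = 0.0259). Hspa1a, an inducible chaperone of the Hsp70 family, rose by 2.88 ± 0.34 (SE, adjusted p = 0.031), and Fos, a subunit of the AP-1 transcription factor, rose by 2.63 ± 0.29 (SE, adjusted p = 0.0291).

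In all, 36 of 10167 features passed the threshold, 2 higher and 34 lower at week 9, and 1628 had an unadjusted p under 0.05. Ces1d, a carboxylesterase abundant in fat tissue, was at least 6.44-fold lower at week 9, where neither array was above background (adjusted p = 0.0391). Plau, the urokinase plasminogen activator, was at least 3.95-fold lower (adjusted p = 0.0259) and Cd300lg, a receptor of capillary endothelium, at least 3.42-fold lower (adjusted p = 0.0481). Vcam1, a vascular and stromal adhesion molecule, fell by 1.47 on the log2 scale (adjusted p = 0.0481). Cdkn1b, which encodes a cell cycle inhibitor, fell by 2.24 on its brightest probe and by 0.97 on the other, while Nfib went from a mean log2 signal of 7.90 to 5.90, Zbtb38 changed by -2.05 and Polh, a translesion DNA polymerase, by -2.12, with adjusted p from 0.0182 to 0.031. Meis2, a homeobox transcription factor, was at least 2.99-fold lower and Cidea, a lipid droplet protein, at least 2.32-fold lower (adjusted p = 0.0259 and 0.0346). For some called genes the tested probes differed widely. Sppl2a, a membrane protease, fell by 2.73 on its brightest probe, while its other tested probe changed by -0.67. Usp10, a deubiquitinase, fell by 2.26 on the brightest of 3 probes, and the highest of the 3 was 0.15. Ablim1 was at least 3.02-fold lower on its brightest probe, and the other changed by 0.30. Nsd1 and Ube2z, chosen after their values were seen, changed by -1.66 and -1.36 on the brightest probe and by 0 and 0.08 on the other. Of 6 other background corrections and scalings, 1 of them chosen after the data were seen, Cd300lg passed in 3, Cidea in 4, and Hspa1a, Ablim1, Meis2 and Vcam1 in 5. With the authors' values the log2 change was -1.10 for Adipoq, -0.73 for Plau, -0.59 for Cd300lg and 1.35 for Hspa1a, and Cd300lg, Cidea, Meis2, Ablim1 and Hspa1a did not pass.

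By list, camera called 14 of the 34 at week 9 against week 6, 13 lower and 1 higher. Some lists share members, so their shifts are not independent. C1qa is in the macrophage and complement lists, and Dcn in the fibroblast, collagen and tendon lists. With an estimated correlation none was called, with an adjusted p from 0.342 to 0.472 for the 13 and adjusted p = 0.426 for the 1, and 3 lists had an unadjusted p under 0.05. Fry called none either, with a lowest adjusted p of 0.0862 and 11 lists at an unadjusted p under 0.05. Collagens and matrix genes had a median log2 change of -0.72 (camera adjusted p = 3.89e-10), with 26 of 28 members negative. None of the 28 passed the threshold over all genes, and 9 were lower when adjusted over the list alone. Sparc, a collagen-binding matrix protein, had a log2 change of -1.32 and Col6a1 of -1.21. Adipocyte genes had a median of -0.68 (camera adjusted p = 7.87e-09), with 17 of 19 negative. Adipoq and Cidea passed over all genes, and 9 were lower when adjusted over the list alone. Plin4, a lipid droplet coat protein, had a log2 change of -2.89 (adjusted p = 0.0622).

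Macrophage genes had a median of -0.69 (camera adjusted p = 1.26e-08), with 18 of 20 negative, none past the threshold over all genes and 9 lower when adjusted over the list alone. Mrc1, the mannose receptor, had mean log2 signals of 8.29 at week 6 and 7.29 at week 9, and Timd4, a receptor for dying cells, had a log2 change of -0.97. Complement genes had a median of -0.75 (camera adjusted p = 8.43e-07), with all 13 tested members negative and 3 lower when adjusted over the list alone. Endothelial and angiogenesis genes had a median of -0.90 (camera adjusted p = 2.52e-06), with 20 of 23 negative and 8 lower when adjusted over the list alone. Ramp2 and Plvap, both genes of endothelial cells, had log2 changes of -1.66 and -1.41. Without the first week 6 array the endothelial median was -0.54. With the authors' values it was -0.28, and that of the collagen list was -0.25. Synovial lining and fibroblast genes had a median of -0.46 (camera adjusted p = 2.2e-05) and matrix proteases and inhibitors of -0.60 (camera adjusted p = 2.63e-05). Over all genes, Vcam1 passed in the former and Plau in the latter, and 6 and 3 were lower when adjusted over the list alone. The fibroblast median was -0.28 without the first week 9 array, and the protease median -0.40 without the first week 6 array. Chemokines had a median of -0.47 (camera adjusted p = 0.00212). Cxcl13, which guides B cells, had a log2 change of -1.19 (adjusted p = 0.052), while Ccl3, a chemoattractant for monocytes, had one of 1.56 (adjusted p = 0.0896).

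The remaining lower lists were smooth muscle and pericyte genes at -0.68, neutrophil genes at -0.35, tendon genes at -0.47, erythroid genes at -0.41 and endoplasmic reticulum stress and secretion genes at -0.16. Their camera adjusted p ran from 0.00459 to 0.0292, and no member passed over all genes. The neutrophil list had a median of -0.74 without the second week 6 array and of -0.10 without the first, where it was not called, nor was the smooth muscle list, at -0.42. With no filter on dim probes the smooth muscle median was -0.12. The tendon list was not called without the first week 9 array or either week 15 array, with medians of -0.23 to -0.84 over the arrays left out. It was also not called in a fit of only the arrays compared or with no filter on dim probes, where its median was -0.07. The erythroid list was not called without the first week 9 array or with the authors' values, where its median was -0.12, and stood at -0.09 without the second week 6 array. With no filter on dim probes it stood at -0.01 and was not called, and with the stricter filter at -0.88. The endoplasmic reticulum list was not called without the first week 6 or the first week 9 array, or with scaling to the 75th percentile. Immediate early genes, which respond within minutes to growth factors and stress, had a median of 0.41 (camera adjusted p = 0.0102), with 12 of 17 positive. Fos passed over all genes, and 5 were higher and 1 lower when adjusted over the list alone. Without the second week 9 array the median was 0.09 and the list was not called. Without the second week 6 array the median was 0.24. Beside these shifts, B cell and plasma cell genes had a median log2 change of -0.04 (camera adjusted p = 0.61) and T and NK cell genes of 0.26 (camera adjusted p = 0.0617).

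**Figure D2:**
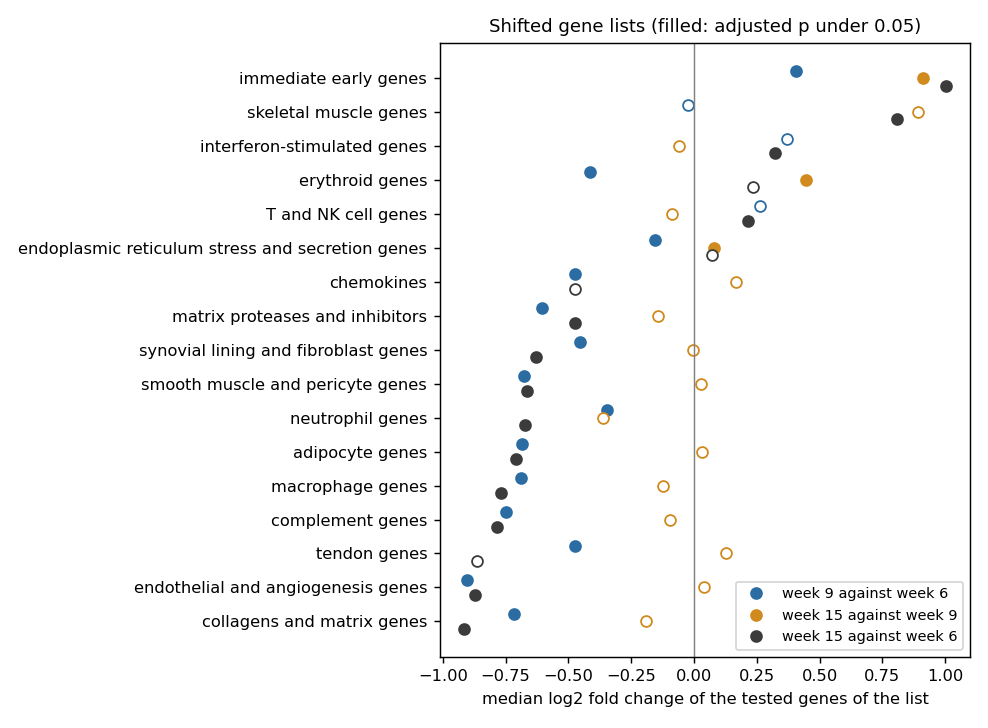
Median log2 fold change (horizontal axis) of the tested genes of each list called in at least 1 comparison (vertical axis), with 1 point per comparison, filled where camera's adjusted p was under 0.05. Collagens and matrix genes lie at -0.72 for week 9 against week 6 and -0.92 for week 15 against week 6, and immediate early genes lie at 0.41 and 1.01. No point stays filled with an estimated correlation.

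Genes of arthritis chosen by name did not pass the threshold between week 6 and week 9. Tnf, which encodes tumor necrosis factor, had a log2 change of 0.15 (SE 0.21), Il1b one of -0.58 (SE 0.19) while Mmp3, which encodes stromelysin, had mean log2 signals of 8.54 and 7.54 (SE of the change 0.44). The alarmin genes S100a8 and S100a9 had log2 changes of -0.44 and -0.61. Il17a had one of -0.05 and Tgfb1 one of 0.32, and Il10 was not above background on either array of both weeks. The counts moved with the array left out, which leaves 1 array in its week. The log2 changes moved less. Over the arrays left out they ran from -2.935 to -2.509 for Adipoq, -2.29 to -2.18 for Cdkn1b and -2.667 to -1.862 for Usp10. All 48 calls of named genes over the 3 comparisons kept their direction with each array left out. Without either week 6 array, or without the second week 9 array, 0 genes passed in limma, with 861, 878 and 843 at an unadjusted p under 0.05. Without the first week 9 array 1 gene passed, without either week 15 array 175 did, and the planned other background corrections and scalings gave 48 to 98.

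The comparison of week 15 with week 9 asked what changed between the peak and resolution. The heat shock gene Hspa1a and the immediate early genes Fos, Fosb and Dusp1 were higher at week 15, and 22 genes that had passed as lower at week 9 were higher again. Hspa1a rose from a log2 signal of 8.61 ± 0.48 to 12.17 ± 0.29 (SD, n = 2), a change of 3.56 with a standard error of 0.34 (limma adjusted p = 0.0159). Fos rose by 3.20 ± 0.29 (SE, adjusted p = 0.0149), Fosb, another AP-1 subunit, by 3.19 ± 0.22 (SE, adjusted p = 0.00884), and Dusp1, a phosphatase of MAP kinases, by 2.15 ± 0.23 (SE, adjusted p = 0.0189).

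In all, 121 features passed the threshold, 99 higher and 22 lower at week 15, and 2361 had an unadjusted p under 0.05. Sppl2a was higher by 3.30 on its brightest probe and by 0.81 on the other. Yme1l1, a mitochondrial protease, was higher by 2.30 on the brightest of 3 probes and by 0.66 on the lowest, and Usp10 by 2.18 and 0.16. Pdcd4, an inhibitor of translation, rose by 2.10 and Zfp457 by 2.60. Tut4, which adds uridines to RNA, was at least 4.39-fold higher, Paip1 at least 4.36-fold and Ablim1 at least 3.40-fold, none of them above background on either week 9 array. The other tested probe of Ablim1 changed by -0.23. Their adjusted p ran from 0.00884 to 0.0478. Among the genes that fell, Ripor1 changed by -1.53 and Sertad3 by -1.28. Mnt, a repressor that pairs with Max, changed by -1.37 on its brightest probe and by -0.22 on the other. Fbxo46 changed by -1.24, Mrgpre by -1.29, Bmf, a proapoptotic BH3-only protein, by -1.17, Htt by -1.12 and Reep4 by -1.08. Galns, a lysosomal sulfatase, was at least 2.15-fold lower, and Galnt9 and Gna15 were at least 1.87-fold lower. Their adjusted p ran from 0.0346 to 0.0461. Of 6 other background corrections and scalings, Galnt9, Gna15 and Mrgpre passed in 3, Galns, Mnt, Bmf, Htt and Zfp457 in 4, and Ripor1 and Fbxo46 in 5. With the authors' values the log2 change was -0.34 for Galns, -0.33 for Galnt9 and -0.31 for Gna15. Washc1 fell by 1.15 on its brightest probe (adjusted p = 0.0327), while its other tested probe changed by 0.47.

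Camera called 3 of the 34 lists between week 9 and week 15, all higher at week 15. Each had adjusted p = 0.563 with an estimated correlation, with which 0 lists were called and 3 had an unadjusted p under 0.05. Fry called 0, with adjusted p = 0.0663 for all 3 and 5 lists at an unadjusted p under 0.05. Immediate early genes had a median log2 change of 0.91 (camera adjusted p = 3.98e-09), with 15 of 17 positive, 8 past the threshold over all genes and 9 when adjusted over the list alone. The median was 0.58 without the first week 9 array, 0.53 without the first week 15 array and 0.51 with no background correction. Klf4 rose by 1.87 on the brightest of 3 probes and by 0.52 on the lowest. Egr1, Junb, Klf6 and Atf3 make up the 8 with Fos, Fosb, Dusp1 and Klf4. Of these, Egr1, Junb and Klf6 were chosen after their values were seen and had log2 changes of 1.57, 1.19 and 0.95. Atf3 was at least 1.73-fold higher and passed in 3 of the 6 other background corrections and scalings. Erythroid genes had a median of 0.45 (camera adjusted p = 0.0115), with the globin gene Hbb-b2 past the threshold at 1.33 and 2 of 9 higher when adjusted over the list alone. The erythroid list was not called without the first week 9 array, with no background correction, at a median of 0.16, with the authors' values, at 0.11, or with no filter on dim probes, at 0.10. Endoplasmic reticulum stress and secretion genes had a median of 0.08 (camera adjusted p = 0.049), with Atf3 past the threshold and 7 of 26 higher when adjusted over the list alone. That call held in 6 of 19 settings and was lost without either week 6 array, the first week 9 array or the first week 15 array. Dnajb9, a chaperone of that compartment, had a log2 change of 0.90 (adjusted p = 0.0592).

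Apart from the erythroid and the endoplasmic reticulum lists, the lists lower at week 9 were not called between week 9 and week 15. Their medians ran from -0.36 for neutrophil genes to 0.17 for chemokines. Collagens and matrix genes stood at -0.19, adipocyte genes at 0.03 and endothelial and angiogenesis genes at 0.04. Skeletal muscle genes had a median of 0.89 (camera adjusted p = 0.0778), which lies in the first week 15 array. None of the genes chosen by name passed. Il1b had a log2 change of 0.90 (adjusted p = 0.076), Saa3, an acute phase protein, one of 1.04 (adjusted p = 0.217), Tnf one of 0.42 and Acp5, an osteoclast phosphatase, one of -0.73. Without the second week 9 array 0 genes passed in limma, with 1175 at an unadjusted p under 0.05. Without the first, 1 passed, without either week 6 array 3, without the first week 15 array 2007 (874 higher and 1133 lower) and without the second 65. With no background correction the split was 244 higher and 111 lower, with the authors' values 220 and 109, and with scaling to the 75th percentile 151 and 12.

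Both steps together separated genes that turned. Of the 34 genes lower at week 9, 22 were higher again at week 15, and none went up at week 9 and down at week 15. Independent lists of these sizes would share 0.331 genes, and unchanged groups simulated with the same shared week 9 arrays gave a mean of 0.01 and at most 1. Both steps use the same pair of week 9 arrays, which were not split between the steps, and the simulation holds no real effects. It also draws every gene and array independently. A deviation shared by both week 9 arrays is not in it, so 22 against 0.01 does not exclude that source. Across genes, the changes of both steps had a covariance of -0.10 against -0.03 in the simulation, and a correlation of -0.547 against -0.4998. The 22 include Sppl2a, Plau, Usp10, Cdkn1b, Polh, Zbtb38, Nfib, Ablim1 and Pdcd4. Adipoq, Ces1d, Vcam1 and Cidea are not among them. Cidea had a log2 signal of 6.32 at week 6, 4.62 at week 9 and 4.53 at week 15. Both Hspa1a and Fos passed upward at each step. The count of 22 was 0 without either week 6 array or the second week 9 array, 1 without the first week 9 array, 93 without the first week 15 array and 32 without the second. The planned other background corrections and scalings gave 35 to 52.

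**Figure D3:**
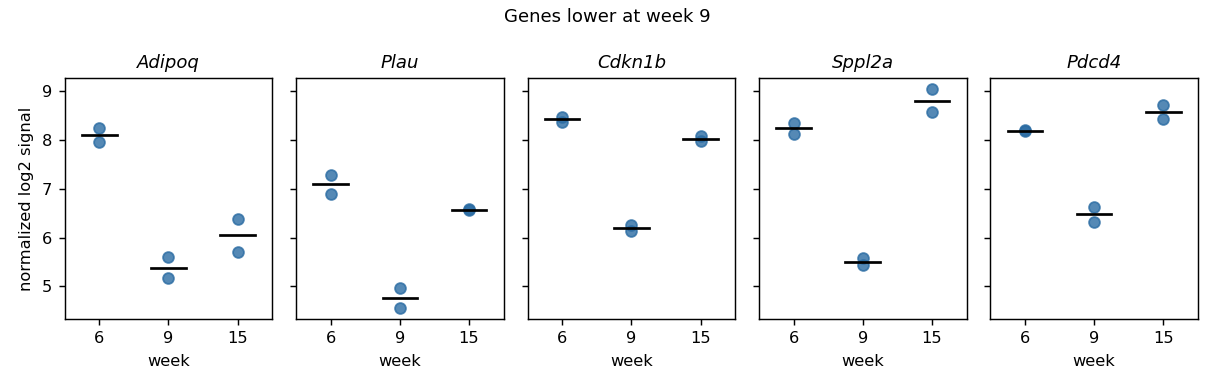
Normalized log2 signal (vertical axis) of 5 genes on each array (points) by week (horizontal axis), with the mean of each week as a bar. Plau, Cdkn1b, Sppl2a and Pdcd4 are lower on both week 9 arrays than on the other 4. Adipoq is lower at week 9 and at week 15 than at week 6, with means of 8.11, 5.38 and 6.05.

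The comparison of week 15 with week 6 asked how far the tissue at resolution differed from that at induction. Just 5 genes passed the threshold, all higher at week 15, and 1464 features had an unadjusted p under 0.05. Hspa1a was 86.7-fold higher, a log2 change of 6.44 ± 0.34 (SE, n = 2 per week, limma adjusted p = 0.00093). Fos was 56.5-fold higher at 5.82 ± 0.29 and Fosb 23.4-fold at 4.55 ± 0.22, both with adjusted p = 0.00093. On the week 6 arrays Fosb had log2 signals of 5.39 and 4.91 and Hspa1a of 6.14 and 5.32. The medians of all genes and unnamed probes there were 5.16 and 5.15. The folds of Fosb and Hspa1a thus depend on the background level. Dusp1 changed by 2.92 ± 0.23 (SE, adjusted p = 0.0092). Ccl3, the macrophage inflammatory protein 1 alpha, changed by 2.91 ± 0.29 (SE, adjusted p = 0.0379). All 5 passed with the authors' values too, at smaller log2 changes of 4.54 for Hspa1a, 5.09 for Fos, 2.35 for Fosb, 2.68 for Dusp1 and 1.68 for Ccl3.

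**Figure D4:**
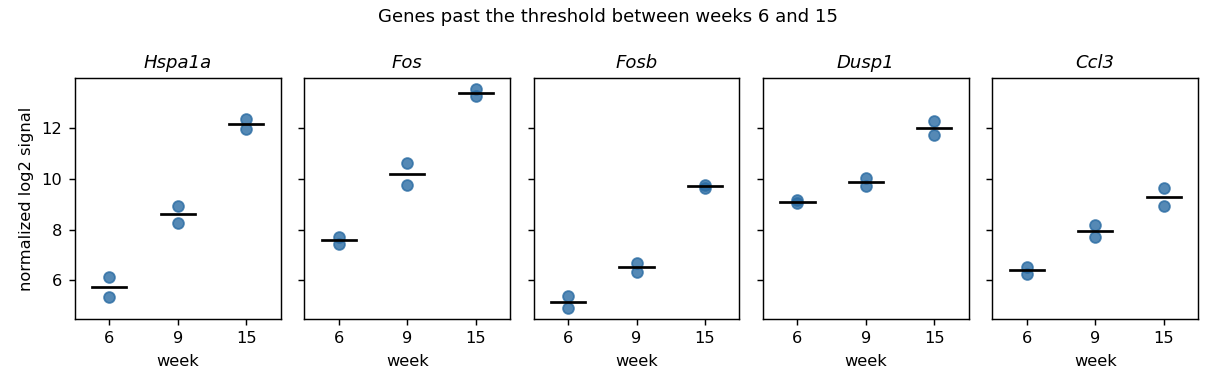
Normalized log2 signal (vertical axis) of the 5 genes past the threshold between week 6 and week 15 on each array (points) by week (horizontal axis), with the mean of each week as a bar. Hspa1a has means of 5.73, 8.61 and 12.17 and Fos of 7.58, 10.20 and 13.40 at weeks 6, 9 and 15.

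Camera called 13 of the 34 lists between week 6 and week 15, 4 higher and 9 lower at week 15. With an estimated correlation 0 were called, with adjusted p from 0.425 to 0.827 and 1 list at an unadjusted p under 0.05. Immediate early genes had a median log2 change of 1.01 (camera adjusted p = 1.52e-14), with 14 of 17 positive, 3 past the threshold over all genes and 12 higher when adjusted over the list alone. Fry called this list too (adjusted p = 0.0462), and also osteoblast and osteocyte genes, lower with a median of -0.48 (fry adjusted p = 0.0259, camera adjusted p = 0.0744). Klf4 did not pass (adjusted p = 0.0599), with log2 changes of 2.40 on the brightest of 3 probes and 0.52 on the lowest. The brightest probe lay near background at week 6, at log2 signals of 4.81 and 4.61, so the size of its change depends on the background level.

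The 9 lower lists had no member past the threshold over all genes. Collagens and matrix genes had a median of -0.92 (camera adjusted p = 2.04e-12), with all 28 tested members negative and 19 lower when adjusted over the list alone. Col6a1 had a log2 change of -1.59 (adjusted p = 0.0801), Eln, which encodes elastin, one of -1.01 and Ogn one of -0.99. Macrophage genes had a median of -0.77 (camera adjusted p = 1.05e-09), with 20 of 20 negative and 14 lower when adjusted over the list alone. Mrc1 had a log2 change of -1.07 and Cx3cr1, the fractalkine receptor, one of -1.10. The macrophage median was -0.48 without the second week 15 array. Neutrophil genes had a median of -0.67 (camera adjusted p = 4.99e-06), with 15 of 18 negative and 9 lower when adjusted over the list alone. Camp, which encodes an antimicrobial peptide, had a log2 change of -2.17 and Mpo, which encodes myeloperoxidase, one of -1.46, both with adjusted p = 0.0599. Ltf, which encodes lactoferrin, had one of -1.95.

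Adipocyte genes had a median of -0.71 (camera adjusted p = 9.18e-07), with Adipoq at -2.06 (adjusted p = 0.0599) and 7 of 19 lower when adjusted over the list alone. The adipocyte median was -0.36 without the second week 15 array. Endothelial and angiogenesis genes had a median of -0.87, complement genes of -0.79, synovial lining and fibroblast genes of -0.63, matrix proteases and inhibitors of -0.48 and smooth muscle and pericyte genes of -0.67. Their camera adjusted p ran from 5.55e-06 to 0.00314. Without the second week 15 array the smooth muscle list had a median of -0.25 and was not called, the endothelial median was -0.43 and the complement median -0.46. Without the first week 15 array the smooth muscle and endothelial medians were -1.04 and -1.42. Without the first week 6 array the medians were -0.55 for endothelial, -0.39 for fibroblast, -0.28 for protease and -0.42 for smooth muscle genes. With the authors' values the collagen median was -0.30 and the endothelial median -0.29. Within these lists, with the main processing, Mmp2, a gelatinase, had a log2 change of -1.38, Vcam1 of -1.26 and C4b, a complement component, of -1.58. The arrays of 1 week differed for C4b, with log2 signals of 11.54 and 10.85 at week 6 and of 10.4 and 8.83 at week 15.

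The other 3 higher lists had no member past the threshold over all genes. T and NK cell genes had a median of 0.22 (camera adjusted p = 0.00692), with 19 of 22 positive and none called over the list alone. Cd3g, a subunit of the T cell receptor complex, had a log2 change of 0.56. Without the first week 15 array the T and NK cell list had a median of 0.16 and was not called. Interferon-stimulated genes had a median of 0.32 (camera adjusted p = 0.0116), with 24 of 25 positive and Bst2 the exception at -1.21. Gbp3 and Gbp2, interferon-induced GTPases, had log2 changes of 0.81 and 0.58. The interferon list was not called without the first week 6 array, at a median of 0.06, or without the second week 15 array, at -0.04. Its median was 0.81 without the second week 6 array and 0.82 without the first week 15 array. Skeletal muscle genes had a median of 0.81 (camera adjusted p = 0.0121), which rests on 1 array. Without the first week 15 array their median was -0.37 and the call turned to lower (camera adjusted p = 0.0278).

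None of the other genes chosen by name passed between week 6 and week 15. Col1a1, a main collagen of bone and fibrous tissue, had a log2 change of -1.10 (SE 0.33) and Ctsk, a collagen-degrading protease of osteoclasts, one of -0.97 (SE 0.19). Tnf had one of 0.56 (SE 0.21), Mmp3 one of -1.24 (SE 0.44) and Il1b one of 0.33 (SE 0.19). Arrays of 1 week differed widely for Col1a1, with log2 signals of 6.95 and 5.85 at week 6 against 5.33 and 5.27 at week 15. So they did for Mmp3, with 9.07 and 8 at week 6 against 7.87 and 6.73 at week 15. The reference genes Rps3 and Ywhaz had log2 changes of 0.24 and 0.49. Without either week 6 array 3 genes passed, without the first week 15 array 1019 did (377 higher and 642 lower) and without the second 23. The 5 were called under every one of the 5 planned other background corrections and scalings, which gave 10 to 44 genes, with 22 higher and 22 lower under the normal-exponential correction fitted on the probes.

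Over the 3 weeks together, 63 features passed the moderated F test, and 2254 had an unadjusted p under 0.05. The mean was lowest at week 9 for 45 of the 63 and highest at week 15 for 41 and at week 6 for 22. For none was it highest at week 9. Without the second week 9 array 3 features passed, without the first week 9 array or either week 6 array 4 did, without the first week 15 array 1666 and without the second 100. Of the 34 lists, camera called 17 in no comparison, and fry called 1 of these, osteoblast and osteocyte genes between week 6 and week 15. Their medians ran from -0.34 to 0.23 between week 6 and week 9, from -0.30 to 0.31 between week 9 and week 15, and from -0.48 to 0.09 between week 6 and week 15. They hold the lists of proinflammatory cytokines and receptors, B cells, mast cells, dendritic cells, resolution mediators, osteoclasts, osteoblasts, cartilage, Wnt and BMP signalling, epidermis, nerve, cell cycle, hypoxia, oxidative phosphorylation, ribosomal proteins, NF-kappaB and integrins. The lowest camera adjusted p among them was 0.0744, for osteoblast and osteocyte genes between week 6 and week 15.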

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

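The variant with all control rows in the background set was chosen after the data were seen, and all others before. The median intensity was 99.07 to 129.5 against a mean background of 86.88 to 111.2, and the number of arrays limits the precision. The log2 differences within the week 15 pair had an SD of 0.510, against 0.299 at week 6 and 0.303 at week 9. Hspa1a, Fos and Fosb passed between week 6 and week 15 in 18 of 18 settings, Dusp1 in 16 and Ccl3 in 11. Counts within 1.5 times of those reported came from no filter on dim probes, a minimum of 1.5-fold and all control rows. The cause of the changes below was not tested, except where fewer arrays, another threshold or another test makes them. Values follow the order week 9 against 6, week 15 against 9, week 15 against 6, any change over 3 weeks, and genes that turned, unless named.

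With no background correction these were 69, 355, 29, 201 and 43 genes, and 1 list was called between week 9 and week 15. With the normal-exponential correction fitted on the probes they were 90, 321, 44, 208 and 52. Scaling to the 75th percentile gave 83 between week 6 and week 9, 10 between week 6 and week 15, 117 over 3 weeks and 44 turned. Cyclic loess gave 98, 199, 26, 154 and 50. The authors' values gave 329 between week 9 and week 15, 15 between week 6 and week 15, 95 over 3 weeks, 35 turned and 1 list between week 9 and week 15. The stricter filter gave 60, 224, 27, 149 and 34. With every probe on its own 71, 328, 162 over 3 weeks and 44 turned passed. A variance trend with robust estimation gave 97, 344, 61, 217 and 56. A fit of only the 4 arrays compared gave 175 between week 6 and week 9, 3 between week 9 and week 15 and 1 turned. An adjusted p of 0.10 gave 126, 493, 52, 301 and 74, and a test against a change of 1.2-fold gave 19, 35 and 10 turned. With an estimated correlation camera called 0, 0 and 0 lists, with 3, 3 and 1 at an unadjusted p under 0.05. Fry called 0, 0 and 2 lists, with 11, 5 and 9 at an unadjusted p under 0.05.

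With the replicate number as a block, 8 genes passed between week 6 and week 9, 38 between week 9 and week 15, 4 between week 6 and week 15, 9 over 3 weeks and 5 turned. Deviations of the first arrays from their group means correlated across genes at -0.0389 between weeks 6 and 9, 0.154 between weeks 6 and 15 and -0.0823 between weeks 9 and 15. These values were not tested, so whether arrays with the same number share more than the number is not known. A block by slide was not run, since no slide is given in the sources used here.

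With each array left out in turn, limma gave 0 to 175 genes between week 6 and week 9, 0 to 2007 between week 9 and week 15, and 3 to 1019 between week 6 and week 15. Over 3 weeks 3 to 1666 passed, and 0 to 93 turned. Of the lists, 11 to 18, 1 to 9 and 11 to 15 were called. A week left with 1 array is assumed to vary like the other groups. The counts of 0 had 843 to 878 genes at an unadjusted p under 0.05 between week 6 and week 9 and 1175 between week 9 and week 15. The highest gene counts came without the first week 15 array, or without either week 15 array between week 6 and week 9. Skeletal muscle genes turned without the first week 15 array, with a median of -0.37 between week 6 and week 15 against 0.81, and 2.11 without the second. That array alone held high muscle signal. Without it, the median of all genes moved to -0.107 between week 9 and week 15. The second week 15 array stood further from the other weeks. Its Pearson's r with the week 6 and week 9 arrays was 0.964 to 0.9704, against 0.978 to 0.9844 for the first. Without the first, week 15 is represented by this more distant array alone.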

Other observations

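Of the tests below, those of single probes, of scaling, of background correction and of the dimmer array were chosen only after the result was seen. Ccl21a, which encodes a chemokine of lymphoid tissue, had mean log2 signals of 12.20, 11.28 and 10.66 at weeks 6, 9 and 15. Glycam1, an adhesion ligand of lymph node venules, had means of 10.34, 8.70 and 8.28, and Ccl19 had means of 11.30, 10.75 and 10.22. These 3 genes were chosen after their values were seen, and none passed the threshold in any comparison, with a lowest adjusted p of 0.207. Ribosomal protein genes had median log2 signals of 14.32 to 14.44 on the 6 arrays, and oxidative phosphorylation genes of 10.99 to 11.34.

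Lymphocyte genes had bright signals and cartilage and bone genes lay near background on all 6 arrays. A test of entry with the peak was dropped, since a pattern that holds week 6 by definition had already fixed its outcome. The B and T cell lists together changed by a median of 0.072 between week 6 and week 9 (95% bootstrap interval -0.043 to 0.217), with 24 of 42 genes positive. Lymph node tissue in the dissected samples may account for the signals and could not be decided. Of its markers 13 of 23 (56.5%) were detected on all 6 arrays against 45% of all genes (Fisher's exact test, p = 0.299). These 13 were 4 of 14 vessel and stroma genes (28.6%) and 9 of 9 follicular B cell genes, 2 of which are in another list. The follicular genes restate the bright B cell signal to be explained, so the pooled share cannot decide. The vessel and stroma genes lay below the share of all genes. In contrast, Ccl21a, Glycam1 and Ccl19, chosen after their values were seen, had bright signals.

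In all, 22 genes fell at week 9 and rose at week 15. With 2 other scalings of the same background-corrected values, 22 of 22 passed at both steps. Their turn thus does not rest on the choice among these scalings. The median change of all genes between week 6 and week 9 was 0.0792 with the 75th percentile and 0.00137 with cyclic loess, against 0.0395. Scalings that differ so little could hardly undo the changes of genes selected for passing, so scaling in general was not decided. Background correction that widens the changes could not be decided: 63.6% kept 50% or more of both changes without correction and 90.9% with the other correction, and 19 and 20 passed at both steps. With the authors' values 27.3% did and 15 passed; this and scaling were first 1 test, split after 27.3% was seen, and the authors' values were then taken out because their scaling may differ too. Signal of single probes may account for part. The other probes of 6 of these genes had a median change of -0.004 (95% bootstrap interval -0.822 to 0.19) against -2.031, though Cdkn1b and Sppl2a were lower on both probes. The probes behind -2.031 were the brightest of each gene and were selected for passing at both steps. Part of the gap may come from that selection. A change of stage stays open, untested.

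Fos and Hspa1a passed as higher at both steps, and Fosb, Dusp1 and Ccl3 between week 6 and week 15. The 5 genes that passed between week 6 and week 15 kept 101% to 112% of their log2 change without the dimmer second week 15 array. Their change thus does not rest on that array. They had been selected for passing with both week 15 arrays, which requires that these arrays agree. The test could therefore hardly fail and does not decide on the lower brightness. Stress of the tissue that grew with week is a candidate explanation that could not be decided. Between week 6 and week 15, 14 other heat shock genes had a median change of 0.167 (95% bootstrap interval 0.03 to 0.647, 10 of 14 positive). Between week 6 and week 9 it was 0.027. The interval draws genes and does not measure the spread between arrays. None of the 14 passed between week 6 and week 15, with a lowest limma adjusted p of 0.22. Of those with larger changes, Hsp90aa1 (1.1) and Cacybp (0.73) were not detected on all 6 arrays, while Hspe1 (0.78) and Dnajb1 (0.65) were. The median of 0.167 is far below the 6.44 of Hspa1a. Whether handling or the stage of disease differed cannot be separated, since each week is 1 stage and RNA integrity is given only as a mean.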
